A study of Homo sapiens with 2 samples.

How the data were processed

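The series holds 1 ChIP-seq library made with an antibody against ING5 in HepG2 cells, a human liver cancer line, and 1 input DNA library from the same line. ING5 is a plant homeodomain protein that reads methylated histone H3 and is a subunit of MYST histone acetyltransferase complexes. The ChIP library came with 1 peak list; the input has no file of its own here and entered only as the control of that list. Cells were untreated, and each group has 1 library, so no value has a replicate and no difference between conditions was tested.

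Peaks were called with MACS2 2.1.1.20160309 in paired-end mode at a p cutoff of 1e-05, per the file headers. The headers give 12416160 ChIP fragments (12416135 after filtering), 9915170 input fragments (9915132 after filtering) and a fragment size of 183 bp. They call the ChIP library by a name that no label uses. The tools fastp 0.19.6, Bowtie2 and deepTools are named per the submitters' processing notes, which give no version for the last 2. The deposited pileup is a coverage signal, the number of fragments over the summit. The deposited significance columns are −log10 p and −log10 q, although the headers say that q was not calculated, so peaks were ranked by −log10 p. The deposited fold enrichment is a linear ratio of pileup to local background, as the authors' peak caller computed it. All of these are the authors' values for single peaks and were used only to describe, rank or filter peaks within this list.

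The labels name GRCh37, but the list holds sequence names that belong to GRCh38. The build was settled from the peaks: 1175 summits (13.7%) lay within 1000 bp of a protein-coding transcription start site (TSS) at its GRCh37 position, and 6527 (76.0%) at its GRCh38 position. Coordinates are therefore given as in the list and read as GRCh38. GRCh38 positions of genes were taken from the original positions that the GENCODE 44 annotation records for each exon; no coordinate was converted. The genome sequence at hand was GRCh37, so the planned tests of base content and motifs inside peaks were not run. In their place, promoter sequence was read in GRCh37 and joined to genes by identifier, which gave sequence for 19804 genes (99.9%).

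A promoter peak had its summit within 1000 bp of a TSS of a protein-coding gene. Peaks were then classed as promoter, exon, intron or intergenic, in that order, against protein-coding genes. Each class was set beside 1000 random placements of the same peaks, with chromosome and width kept. Placements fell between the first and last annotated gene of a chromosome, outside gene-free stretches over 2 Mb, in place of the planned exclusion of assembly gaps. The p over placements was doubled from the side seen, and its smallest possible value is 0.00200. Medians were compared by a two-sided permutation test over peaks with 100000 resamples, whose smallest possible p is 1e-05. Shares have exact binomial 95% intervals and peak rates exact Poisson 95% intervals, which cover counting error only.

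The 26 gene lists were fixed before the data were examined. Each was compared with all other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 26 lists, at a threshold of 0.05. The genes FAS and PECAM1 had no GRCh38 position and were left out of their lists. Peaks, genes and placements are not replicates, so every p describes this 1 library. The local background of a peak was recovered from its pileup and fold enrichment, with a pseudocount of 1 on both. Its lowest value, 0.853 fragments, was taken as the genome-wide background, and 5204 peaks lay within 0.001 of it.

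Genes were named from sets fixed in advance: the 15 genes whose promoter peak ranked highest, the 5 highest peaks outside promoters, the 3 widest peaks, ING5, KAT7, KAT6A and KAT6B, and up to 3 members of each list with the most significant peaks. A gene outside those sets was chosen after its values were seen, and the text says so. Motif odds ratios were stratified by 10 classes of promoter CpG observed over expected.

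Alternatives kept the more significant of 2 equal parts of the peaks, the part with the higher fold enrichment, or the 1000 most significant. Others used windows of 3000 bp or 200 bp, any overlap with the window, at least as much of the peak inside the window as outside, all annotated genes, or the nearest gene within 50000 bp. Another left out the 29 densest 1 Mb bins, and random lists were matched on gene length and compared by share of genes with a peak, in place of the planned median rank. Added after seeing the data were peaks at the genome-wide background alone, canonical transcripts alone, and lists matched on promoter CpG. The list test was tested on simulated data: over 20 draws with 19819 genes, 52 of 60 lists with a raised rate were called, and 8 of 460 other lists were called too. The simulated rate was set below the share of genes with a peak in the data, and genes were drawn without regard to promoter CpG. Those counts therefore do not give the rates of right and wrong calls for the real lists. The number of draws and the recovery required were set after a version with a single draw had called an unaltered list. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.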

Results

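ING5 occupancy was profiled by ChIP-seq in untreated HepG2 cells to find the genes that the protein binds. The ING5 library held 12416160 fragments and the input library 9915170. With 1 library of each kind there was no replicate error, so intervals covered counting error only and every test described this 1 peak list. All positions are GRCh38.

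The peak list held 8608 peaks, and the strongest ones by fold enrichment lay at TFAP2A, which encodes a developmental transcription factor, and in MIRLET7BHG, the host gene of let-7 microRNAs. The peak at TFAP2A reached 63.2-fold over background with 118 fragments at its summit, and the strongest in MIRLET7BHG reached 57.0-fold with 131 fragments. Most peaks were far lower and narrow. The median fold enrichment was 6.47, with quartiles of 5.40 and 8.01, and the median pileup was 12 fragments. The median width was 338.5 bp (95% interval 333 to 345), and 58 peaks were wider than 2000 bp. The widest covered 11697 bp on chromosome 6 from 10409253 to 10420949, across the 5′ part of TFAP2A and the antisense gene TFAP2A-AS1. The next widest, of 6905 bp and 4984 bp, both lay in MIRLET7BHG on chromosome 22.

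ING5 peaks gathered at the start of protein-coding genes. Of the 8589 peaks on chromosomes 1 to 22 and X, 6527 (76.0%, 95% interval 75.1 to 76.9) had their summit in a promoter, against 5.40% ± 0.247 (SD of 1000 random placements). Introns held 10.7% of summits against 40.3% in placements, and intergenic sequence 10.1% against 51.3%. These 3 shares lay outside every placement, with the smallest possible p of 0.00200 each. Exons held 3.24% against 2.96%, a difference that did not pass the test over placements (permutation p = 0.132). In the more significant of 2 equal parts of these peaks exons held 1.96%, below the 2.92% of placements (permutation p = 0.00200).

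Within promoters the summits lay mainly downstream of the TSS. Of 6609 summits within 3000 bp of a canonical TSS, 85.7% (84.8 to 86.6) lay downstream. The fullest 100 bp bin ran from 200 to 300 bp downstream and held 814 summits, while the first 100 bp downstream held 222 and the last 100 bp upstream held 48. A smaller upstream group was fullest between −400 and −300 bp, with 119 summits. Measured to any annotated TSS of a protein-coding gene, canonical or not, the promoter share with a window of 200 bp was 31.5%. Within 200 bp of a canonical TSS lay 911 summits (10.6%).

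**Figure D1:**
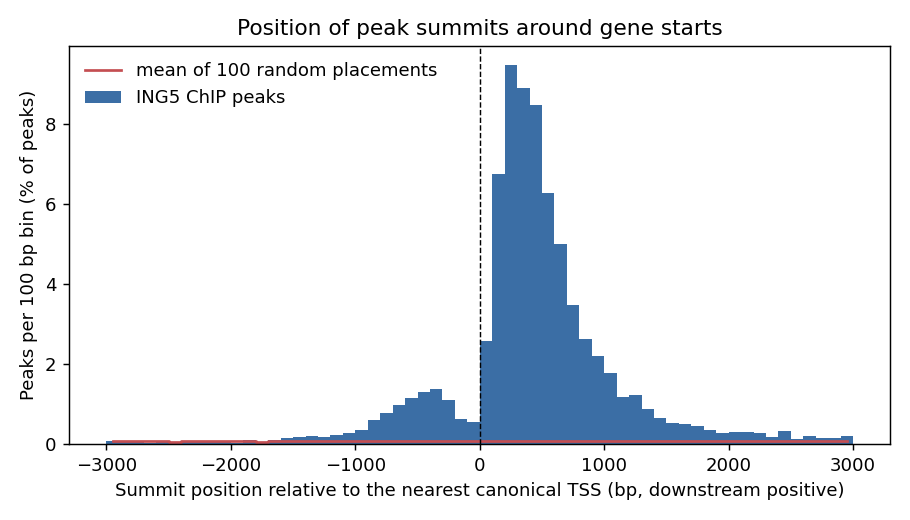
Share of peak summits (%) in 100 bp bins by their signed distance (bp) to the nearest canonical TSS of a protein-coding gene; blue bars are the ING5 peaks and the red line is the mean of 100 random placements. The fullest bin lies 200 to 300 bp downstream with 814 summits, and the fullest upstream bin, −400 to −300 bp, holds 119.

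Promoter peaks were stronger and wider than other peaks. The median fold enrichment was 6.66 at 6527 promoter peaks and 5.40 at the 2062 others, and the median width was 365 bp against 263 bp. Both differences reached the smallest p of the two-sided permutation test over peaks, 1e-05. The difference in fold did not hold among the 1000 most significant peaks, where it was −0.301 (permutation p = 0.138).

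Besides TFAP2A, the promoters with the most significant peaks included that of IGF2BP3, an RNA-binding protein gene of fetal and tumour tissue. It reached 39.9-fold, with its summit 59 bp from a TSS. RUNX1, a transcription factor gene of blood development, reached 29.1-fold, and CDKN1B, which encodes the cell cycle inhibitor p27, 25.9-fold. HOXA9 reached 26.98-fold, as did the overlapping genes HNRNPUL2 and HNRNPUL2-BSCL2, which shared 1 peak. HNRNPU, a nuclear RNA-binding protein gene, reached 23.1-fold, the condensin subunit gene SMC4 23.5-fold, the integrin gene ITGB8 24.3-fold and BAHCC1 23.7-fold. On chromosome 5, MRPS30, GOLPH3 and OSMR reached 15.35-fold, 16.1-fold and 14.4-fold over local backgrounds of 3.49, 2.78 and 3.57 fragments, all above the genome-wide 0.853.

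Outside promoters, the most significant peak of the list was unlike the rest. It covered 261 bp on chromosome 1 from 125180080 to 125180340, in sequence without annotated genes, with 807 fragments over a local background of 119.6, which made 6.70-fold. Another peak in intergenic sequence of chromosome 1, from 143214661 to 143214856, had 165 fragments over a background of 15.7. The other 3 were wide peaks near long noncoding RNA genes. Of these, 2 lay in MIRLET7BHG, with 57.0-fold and 41.5-fold enrichment. The third reached 46.2-fold on chromosome 12 from 12723398 to 12725187, with its summit 143 bp from a long noncoding RNA start and 2049 bp from a TSS of APOLD1.

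Peaks formed runs at TFAP2A, over the HOXA cluster and in MIRLET7BHG. The TFAP2A window of 40 kb held 6 peaks with 9 to 118 fragments. The HOXA window of 120 kb held 23 peaks with 8 to 56 fragments, and the tallest ran from 27191187 to 27194141 on chromosome 7, with its summit between HOXA11 and HOXA13. The MIRLET7BHG window of 65 kb held 20 peaks with 7 to 131 fragments. These 3 windows were chosen after the peaks were seen.

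**Figure D2:**
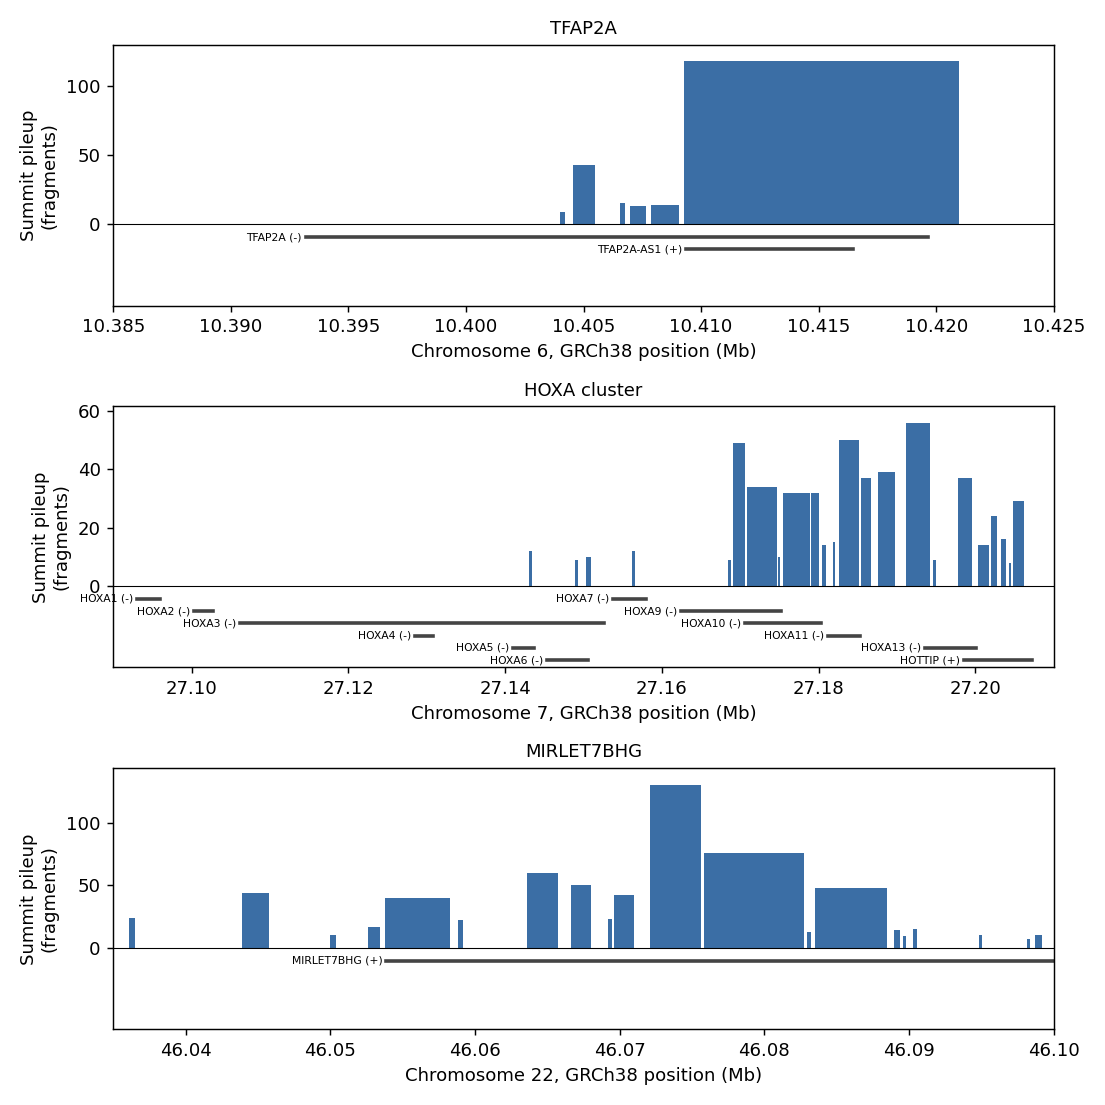
Peaks in windows at TFAP2A, the HOXA cluster and MIRLET7BHG, by GRCh38 position (Mb); each blue box spans a peak and its height is the pileup at the summit (fragments), and dark lines are genes with their strand. The windows hold 6, 23 and 20 peaks, with highest pileups of 118, 56 and 131 fragments.

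Peaks were densest on chromosome 19, with 8.10 per Mb (95% Poisson interval 7.36 to 8.89), followed by chromosomes 22 with 6.87, 17 with 6.67 and 16 with 6.23. They were sparsest on chromosome 4, with 0.777 per Mb, and on the X chromosome, with 0.782. By genes the order was another: 21.1% of the genes of chromosome 19 had a promoter peak (19.1 to 23.3), against 42.6% on chromosome 15 and 40.1% on 16. The rate over all chromosomes was 3.02 per Mb, and 11 chromosomes lay above it, 10 below it and 2 had intervals that held it. On chromosome 5, 69.3% of peaks stood over a local background above the genome-wide one, the highest share of any chromosome, against 15.3% on X. Any excess over 0.001 fragments counted as above. The median local background was 1.25 fragments on chromosome 5 and 0.853 on X, so many of these raises were small.

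**Figure D3:**
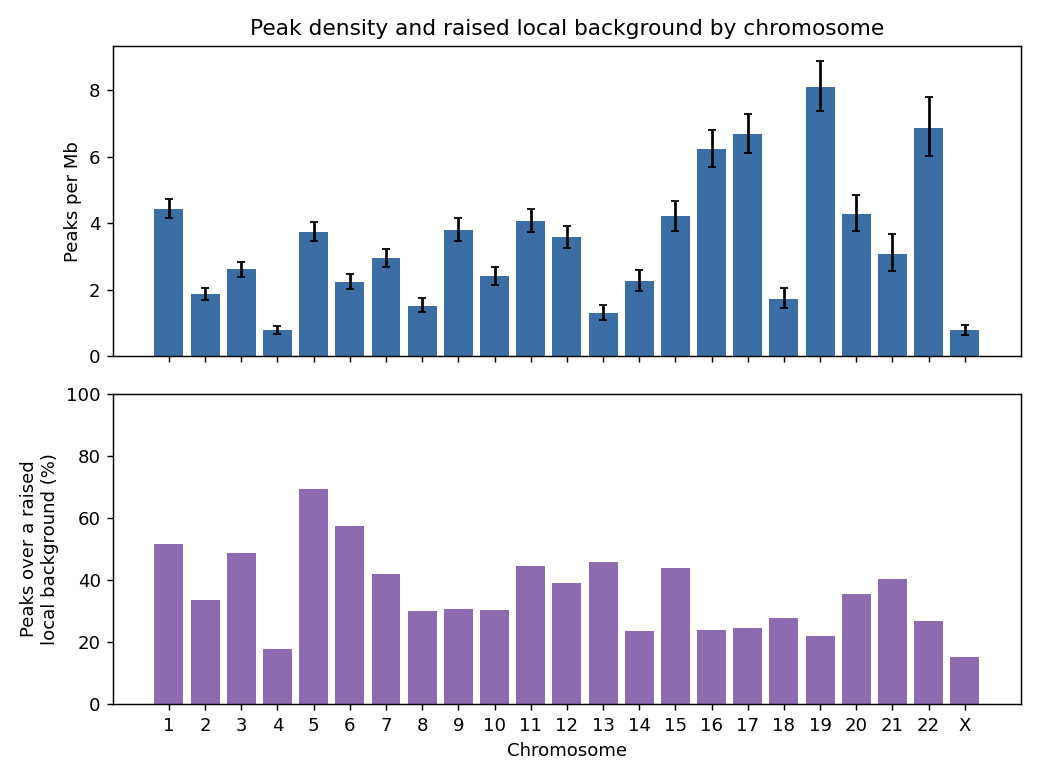
Peaks per Mb on each chromosome with exact 95% Poisson intervals (top), and the share of peaks (%) whose local background lay above the genome-wide one (bottom), in 1 ING5 library. Chromosome 19 has the highest density, 8.10 per Mb, and chromosome 5 the highest share over a raised background, 69.3%.

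A promoter peak was found at 6126 of 19812 protein-coding genes (30.9%, 30.3 to 31.6). Cytosolic ribosomal protein genes and genes of cholesterol and fatty acid synthesis stood furthest above that share. The ribosomal genes had a peak at 69 of 83 (83.1%, adjusted exact p = 1.15e-21 by Fisher's exact test), led by RPL13 with 20.5-fold, RPL10A with 17.7-fold and RPL37 with 12.3-fold. Genes of cholesterol and fatty acid synthesis had a peak at 21 of 25 (84.0%, adjusted exact p = 3.15e-07), led by FASN and SCD, enzymes of fatty acid synthesis and desaturation, with 15.6-fold and 14.2-fold, and SREBF1, a regulator of both pathways, with 15.1-fold.

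Genes of DNA replication and the cell cycle were also bound more often than other genes. The share was 26 of 38 for DNA replication (adjusted exact p = 1.27e-05), where the helicase gene MCM2 led with 14.03-fold, ahead of POLA2 and the licensing factor gene CDT1 with 9.17-fold each. It was 20 of 31 for cell cycle regulators (adjusted exact p = 3.33e-04), with CDKN1B at 25.9-fold, MYC at 18.3-fold and CDKN2C at 15.98-fold. Replication-dependent histone genes had a peak at 37 of 64 (adjusted exact p = 3.35e-05), from 29 distinct peaks, since neighbouring genes such as H2AC15 and H2BC15 shared 1; H4C9 led with 14.7-fold. Among peaks at the genome-wide background the histone list was below other genes, at 4.69% (adjusted exact p = 0.00264), and with a window of 200 bp it was at 7.81% (0.317). The first setting drops peaks over a raised background, and genes left with no other peak count as without one. The best peak of H4C9 stood over 1.58 fragments, and that of H2AC15 and H2BC15 over 1.60. The lower share there therefore follows at least in part from the filter. The call of the histone list as one with more peaks was lost under 4 of 12 alternatives, and those of DNA replication and cell cycle regulators under 1 each.

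Stress, survival and growth signalling genes followed. Targets of p53 had a peak at 16 of 24 (adjusted exact p = 8.24e-04), with PHLDA3 at 12.9-fold and SESN2 and PMAIP1 at 9.17-fold each. Genes of PI3K and Akt signalling also had 16 of 24 (adjusted exact p = 8.24e-04), with PIK3CA at 10.7-fold and RICTOR at 9.02-fold among them. Apoptosis genes had 15 of 25 (adjusted exact p = 0.00557), with MCL1 at 15.6-fold, TNFRSF1A at 14.03-fold and FADD at 10.8-fold, a call lost under 4 of 12 alternatives. Autophagy genes had 14 of 26 (adjusted exact p = 0.0229), led by SQSTM1 with 12.4-fold, a call lost under 8 of 12 alternatives; those of p53 targets and of PI3K and Akt signalling were lost under 2 each.

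Energy and protein turnover genes were above other genes as well. Complex I subunit genes had a peak at 22 of 37 (adjusted exact p = 8.24e-04), led by NDUFS6 with 14.2-fold. Proteasome genes had 23 of 39 (adjusted exact p = 7.68e-04), led by PSMD2 with 12.4-fold. Core spliceosome genes had 18 of 33 (adjusted exact p = 0.0102), led by SRSF2 with 21.04-fold. Glycolysis genes had 13 of 24 (adjusted exact p = 0.0301), led by PKM with 15.98-fold, ENO1 with 16.2-fold and LDHA with 11.9-fold. Of 12 alternatives, 6 ended the call of the spliceosome list, 5 that of glycolysis, 3 that of complex I and 2 that of the proteasome.

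The ING and MYST acetyltransferase list had a peak at 15 of 27 genes (55.6%, 35.3 to 74.5; adjusted exact p = 0.0145). The acetyltransferase gene KAT6B had the strongest, at 17.3-fold with its summit 38 bp from a TSS, ahead of RUVBL1 with 11.5-fold and JADE2 with 9.71-fold. ING5 itself had 2 promoter peaks, the better of them at 8.63-fold with 15 fragments and rank 1710. KAT7 and KAT6A had no promoter peak at this depth. The call of the list was lost under 3 of 12 alternatives: CpG-matched lists (adjusted permutation p = 0.480), peaks at the genome-wide background (adjusted exact p = 0.0630) and the 1000 most significant peaks (0.572).

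Among the lists with fewer peaks were gene families silent in most cells and markers of other cell types. Olfactory receptor genes had a peak at 3 of 404 (0.743%, adjusted exact p = 8.61e-59): OR51E1, OR51D1 and OR1F1, with 4.27-fold, 3.47-fold and 3.996-fold. No peak was found at 94 keratin-associated protein genes (upper bound 3.85%, adjusted exact p = 7.58e-15), 51 clustered protocadherin genes (6.98%, 8.22e-08), 25 blood cell markers (13.7%, 3.33e-04) or 19 fibroblast and endothelial markers (17.6%, 0.00281). Zinc finger genes had a peak at 118 of 504 (23.4%, adjusted exact p = 3.95e-04), led by ZNF195 with 8.96-fold, ZNF692 with 14.03-fold and ZNF622 with 10.6-fold. Of 12 alternatives, 5 ended the call of the fibroblast and endothelial markers, 3 that of the blood cell markers and 2 that of the keratin-associated proteins, among them CpG-matched lists (adjusted permutation p = 0.341, 0.136 and 0.0638). The zinc finger and protocadherin calls were lost under 1 each. In every setting that ended the call of a list without a peak, that list still had none. Those losses therefore did not come from peaks at these genes. Fewer of the genes compared had a peak there, which limits what lists of this size can show.

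In this library, labelled as from a liver line, liver genes were not among the lists with more peaks. Whether the chromatin came from the labelled line could not be told from these data. None of the 25 hepatocyte secreted protein genes, among them ALB and APOA1, had a promoter peak (upper bound 13.7%, adjusted exact p = 3.33e-04), a call lost under 3 of 12 alternatives. The hepatocyte list had no peak in those 3 settings either. Liver transcription factor genes had a peak at 6 of 23 (26.1%, adjusted exact p = 0.822): NR2F2 with 19.96-fold, TBX3 with 16.2-fold, GATA6 with 9.71-fold, and PROX1, PPARA and RXRA. The hepatic regulators HNF4A, FOXA1, FOXA2 and FOXA3 had none; ALB, APOA1, PROX1, PPARA, RXRA and these regulators were named after their values were seen.

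The lists not told apart from other genes were Wnt pathway genes with 10 of 25 (adjusted exact p = 0.401), epithelial and mesenchymal genes with 9 of 20 (0.243), neuronal genes with 4 of 26 (0.110) and homeobox clusters with 16 of 39 (0.192). WNT5A reached 14.03-fold, DSP 11.5-fold and VIM 9.71-fold, and HOXA11 and HOXA13 20.5-fold each, while the neuronal genes DLG4 and GRIN1 stayed at 6.66-fold and 5.40-fold. Homeobox clusters had more peaks than other genes among the 1000 most significant (20.5%, adjusted exact p = 0.00283) and with a window of 3000 bp (53.8%, 0.0122), but fewer without the densest 1 Mb bins (12.8%, 0.0396), where neuronal genes had fewer too (3.85%, 0.00545). Leaving out those bins drops the peaks of the HOXA cluster, DLG4 and GRIN1 but keeps their genes in the test. These lower shares therefore follow at least in part from the filter.

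Of the 21 lists that passed the threshold, 10 passed it against random lists matched on promoter CpG. Those with more peaks were ribosomal proteins, sterol and fatty acid synthesis, DNA replication, cell cycle, p53 targets, complex I and proteasome, and those with fewer were zinc finger, olfactory receptor and protocadherin genes.

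**Figure D4:**
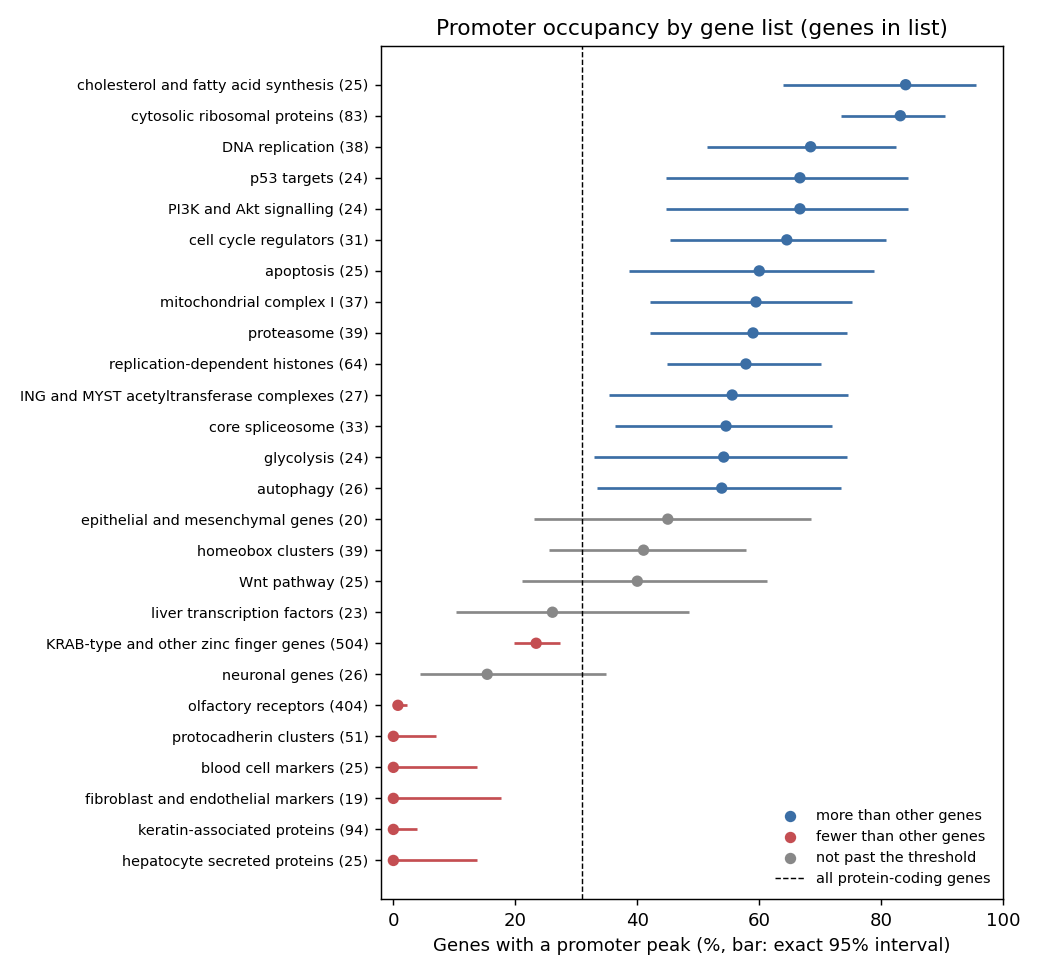
Share of genes (%) with a promoter peak in each of 26 gene lists, with the number of genes in parentheses; bars are exact 95% intervals and the dashed line is the share over all protein-coding genes, 30.9%. Blue marks the 14 lists above other genes after adjustment, red the 7 below and grey the 5 that did not pass the threshold.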

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

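No tests were run in this part. Peaks on sequences outside chromosomes 1 to 22 and X entered none of the comparisons of promoters, genes or chromosomes, although the list holds fragments there. There were 19 such peaks on 14 unplaced, unlocalised or alternative sequences, with 10 to 72 fragments at the summit. The tallest, with 72 fragments, stood over a local background of 13.8 fragments and was 4.94-fold enriched. The peak with the highest enrichment there, 16.7-fold, had 30 fragments over the genome-wide background. No explanation was tested for these peaks.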

How the results depend on the processing

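Tests with peaks at the genome-wide background alone, canonical transcripts alone and lists matched on promoter CpG were chosen only after the results were seen. The promoter share ran from 31.5% to 86.3% over the alternatives and lay above placements in each, and intron and intergenic shares lay below them wherever run. Keeping the more significant 4304 peaks or the 4304 with the higher fold enrichment gave median widths of 473 and 466 bp and median enrichments of 8.01 both times; the 1000 most significant gave 794 bp and 11.3-fold, since each setting keeps stronger peaks by construction. With chromosomal peaks alone split in the same way and order, the exon share of 3.24% was 1.96% and 2.03%, below placements in place of above (permutation p = 0.00200 each), and then 2.90% against 2.91% in placements (permutation p = 1); the cause was not tested. The difference in fold between promoter and other peaks turned to −0.301 among the 1000 most significant (p = 0.138 by permutation), also untested as to cause.

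In place of 21 lists past the threshold there were 5 with the 1000 most significant peaks (4 with more peaks, 1 with fewer), 13 with a window of 200 bp (9 and 4) and 10 against CpG-matched lists (7 and 3), of which 4, 12 and 10 were among the 21. Ribosomal, cholesterol and fatty acid, and olfactory receptor lists passed under all 12 alternatives. Of 312 list results, 243 stayed as they were, 52 lost the call on the same side, 5 gained one on the same side (homeobox clusters in 2 settings, and neuronal, Wnt, and epithelial and mesenchymal genes in 1 each) and 12 changed direction, called or not. Among the 1000 most significant peaks, DNA replication turned to 2.63% and p53 targets to 4.17%, neither told apart from other genes (adjusted exact p = 1 each). Histones turned to 7.81% with a window of 200 bp (0.317) and to 4.69% at the genome-wide background (0.00264), and homeobox clusters to 12.8% both with a window of 200 bp (1) and without the densest bins (0.0396). Liver transcription factors, never called, changed side at 21.7% in both stronger sets, 8.70% in the 1000, and 34.8% with a window of 3000 bp or the nearest gene; Wnt genes, at 40.0%, stood below the mean of CpG-matched lists (adjusted permutation p = 0.670). The genome-wide background setting drops peaks over a raised background, and the setting without the densest bins drops every peak in them. In both, genes left without a peak stay in the test. The turns of histones and homeobox clusters in those settings therefore follow at least in part from the filter. No cause was tested for the other changes. Peak motifs and base content were not run. With 1 library, a median summit of 12 fragments limits what can be called, and no spread between replicates could be measured.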

Other observations

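The tests of chromosomal gains, of the 11p15.4 and 5p regions and of peaks over more than 10 fragments of background were chosen only after the results were seen. The comparison with CpG-matched lists was added once the lists had been seen, and promoter sequence was taken up once the build had been found, with its CpG and motif predictions written before their results. The bounds of the test of collapsed repeats were changed after its values were seen, and under the earlier bounds those values had argued against such repeats. Long noncoding RNA genes held part of the remaining signal. Of the 2062 peaks outside protein-coding promoters, 341 (16.5%, 14.96 to 18.2) had their summit within 1000 bp of a long noncoding RNA TSS, against 1.78% ± 0.301 (SD) and at most 2.77% in 200 random placements. On chromosome 21, the ribosomal DNA copies between 8205988 and 8446572 held 1 peak, with 137 fragments and 5.17-fold enrichment, outside their transcribed parts.

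Promoter sequence differed between genes with and without a peak. The median CpG observed over expected in the 1000 bp centred on the TSS was 0.816 at genes with a peak and 0.650 at the others, and the median G+C was 65.0% against 59.1%. Among liver regulators without a peak, named after their values were seen, the CpG ratio was 0.865 at FOXA1, 0.759 at FOXA3, 0.672 at FOXA2 and 0.368 at HNF4A. Of 18 site types sought in the 500 bp centred on the TSS, 13 were frequent enough to test. After stratification by promoter CpG, genes with a peak more often carried a YY1 site (odds ratio 2.22, 95% interval 1.76 to 2.79) or an ETS site (1.91, 1.70 to 2.15). NRF1 sites had an odds ratio of 1.45 (1.16 to 1.80) and the E-box of MYC 1.14 (1.03 to 1.25), while GC boxes of SP and KLF factors had 0.903 (0.842 to 0.969) and CA repeats 0.543 (0.368 to 0.802). HNF4A and FOXA sites had odds ratios of 0.837 (0.417 to 1.68) and 0.883 (0.711 to 1.096).

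Genes with a peak may be set in part by promoter CpG content. The share with a peak was 4.14% in the lowest of 5 equal classes of promoter CpG and 53.7% in the highest, a ratio of 13.0. Of the sites predicted to go with a peak, those of ETS (odds ratio 1.91, 1.70 to 2.15), NRF1 (1.45, 1.16 to 1.80) and YY1 (2.22, 1.76 to 2.79) met the prediction. NFY sites did not, at 1.04 (0.977 to 1.12), so ETS, NRF1, YY1 and NFY sites as a set stay open. No library with another antibody was analysed here, so a preference of ING5 and a preference of ChIP for open CpG-rich promoters were not separated.

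Hepatocyte secreted protein genes had no promoter peak. Promoters poor in CpG stay open: CpG-matched random lists had a peak at 6.98% of genes and reached down to 0, so the test could not exclude them. Whether more fragments would give these genes peaks was not tested. Chromatin from cells other than the labelled line cannot be told apart either. The test used chromosomes 2, 14, 16, 17 and 20, which general knowledge lists as gained in HepG2. Extra copies there would raise the local background, so the labelled line predicts an odds ratio above 1. The odds ratio of a raised background there was 0.659 (0.578 to 0.751) over all autosomes, first read as fitting other cells. Without chromosomes 1, 3, 5, 6 and 11, left out after their values were seen, it was 0.869 (0.754 to 1.00). Neither set showed the raise predicted for the labelled line. The interval lay below 1 over all autosomes and reached 1.00 in the second set. The reading was changed to open after this second set was seen. The gains were taken from general knowledge and not measured here, so the missing raise does not settle which cells were used. No biological explanation was tested.

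Peaks were dense on 11p15.4 (chromosome 11 from 3000001 to 5000000), with 112 peaks or 56.0 per Mb, and on 5p, with 360 peaks or 7.85 per Mb, and OR51E1 and OR51D1 lie in the former. A raised input background, such as extra copies give, is a candidate explanation: the median local background was 3.40 times the genome-wide one on 11p15.4 and 1.88 times on 5p, against 1.00 times at all other peaks, but 1.33 and 1.25 fragments against 0.853 in the 2 densest 1 Mb bins of 5p. Collapsed repeats stay open, since promoters held 24.1% (16.5 to 33.1) and 31.1% (26.4 to 36.2) of these peaks, above the 10% set as the most that repeats would give but below the 78.7% of all others, and 6.25% in the 5p bin from 1000001 to 2000000. Of the 5 chromosomal peaks over more than 10 fragments of background, 4 (80.0%, 28.4 to 99.5) lay outside promoters and within 5 Mb of a gene-free stretch or chromosome end, against 10.5% of other peaks. Of the 8584 other peaks 903 met both conditions, but 6527 were at promoters and could not. The contrast thus comes in large part from promoters. Repeat copies missing from the assembly could explain the 5 peaks, but the contrast does not decide it. Copy number was not measured here, and no biological explanation was tested.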
